A study of Mus musculus with 10 samples.

How the data were processed

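Small RNA was sequenced from sperm of C57BL/6J mice that had received either saline or tachyzoites of Toxoplasma gondii, an intracellular protozoan parasite, in 5 libraries per group, each made from a pool of 2 mice per the series' design text. Groups were taken from the infection status in the labels, and every library could be assigned. Per the labels' protocols, sperm were released from minced cauda epididymis by swim-up, RNA was extracted with phenol-based lysis and silica columns, and 1000 ng of total RNA entered a small RNA library kit.

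The counts are whole numbers per gene and library as deposited by the authors. Per the submitters' processing notes, which name tools without their order or settings, FastQC, STAR 2.5.3a, featureCounts 1.5.3 from Subread, StringTie 1.3.3, edgeR 3.22.3 and R 3.5.0 were used with builds mm10 and GRCm38. Annotation release, strand setting and treatment of multi-mapped reads are not given in the sources used here. The deposited counts show that multi-mapped reads were counted at each place they map to: the alignments assigned to genes exceeded the mapped reads in 6 libraries, and 77 of the 2874 gene entries with a mean count of at least 20 held the same counts as another entry in all 10 libraries. A read from a short repeated sequence can therefore appear at several genes, and several such genes are named below as sharing counts. Genes in the table that differed by at most 2 counts or 5 percent in every library, among genes with at least 100 counts in all, were treated as sharing counts. The log2 fold changes, log2 average abundances, likelihood ratio scores and p-values in the authors' deposited table carry edgeR column names, per the file headers, and were used only for the comparison named below. A separate deposited table of counts gives total, mapped and assigned reads per library, and mapped reads outside any feature.

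Gene classes and coordinates came from GENCODE release M21 on GRCm38, matched by symbol, with 34874 genes matched and 1886 not matched. Among microRNA genes of that annotation, the table held 35.7% of the 1622 that overlap no exon of another gene, 13.3% of the 420 that overlap one on the same strand and 3.66% of the 164 that overlap one on the opposite strand only. Mir142, Mir155, Mir223, Mir21a and Mir451a are not analysed here, and neither are mitochondrial genes.

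The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1, TMM scaling and Benjamini-Hochberg adjustment at 0.05. Genes were kept by edgeR's filter by expression, with a minimum count of 10 and a minimum total of 15. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM are computed on TMM-scaled library sizes and given as mean ± SD over 5 libraries. Shares of counts and reads were compared by two-sided exact permutation over the 252 assignments of 10 libraries, for which 0.00794 is the smallest possible p. The p-values measure the spread between pools of mice. The test was run on simulated counts for infected against control with 5807 genes: it recovered 70 of 100 genes changed 4-fold and 9 of 100 changed 2-fold, and called 2 unchanged genes. No other genes were changed and no outlying library was simulated. These rates therefore need not hold in the data, where 43.5% of tested genes were called.

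Before the data were examined, 28 gene lists were fixed: let-7, Mir34 and Mir449, miR-10/99/100, miR-30, miR-29 and miR-26, miR-200, miR-17-92, X-linked spermatogenic, Dlk1-Dio3, paternal stress, inflammation and leukocyte microRNAs, markers of erythroid cells, muscle and stroma, epididymal epithelium, spermatids and sperm, and leukocytes, interferon-gamma response genes, mitochondrial tRNAs, mitochondrial mRNAs and rRNAs, nuclear tRNAs, C/D and H/ACA box snoRNAs, spliceosomal snRNAs, Y, vault, 7SK and 7SL RNAs, ribosomal protein mRNAs, piRNA pathway genes and histone mRNAs. The 21 lists with at least 4 tested members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. Tallies of list members below cover tested members only. A scarce gene could pass the filter through its counts in the group where it is higher, which favours members that differ between groups. The mitochondrial lists had no tested member. The H/ACA box and spliceosomal lists were set by symbol prefix and also hold C/D box scaRNAs and U3 and U73B snoRNAs.

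Named genes followed a rule fixed at the same time: among genes past the threshold with a mean count of at least 20, the 12 highest and 12 lowest log2 fold changes with a regular symbol and up to 3 gene models per direction, the 4 members of highest abundance in each list, and the 10 genes of highest share. The rule was applied again without control replicate 1 and with genes sharing counts collapsed, a choice made after seeing the data. Further genes named outside the rule are marked as chosen after their values were seen.

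Table totals ran from 909883 to 2749073 counts per library. The upper 95% confidence limit for a count of 0 is 3 counts, which correspond to 1.09 to 3.30 CPM of the table total. The reads carry no molecular identifiers, so such floors cover counting error only. Alternatives fixed before the data were examined were DESeq2 size factors, library totals and upper-quartile scaling, no filter and a filter of 10 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, robust and older quasi-likelihood code, the replicate number as a block, microRNA genes alone, leaving out the 10 genes of highest share and leaving out each library. Newer quasi-likelihood code and collapsing genes that share counts, alone or without control replicate 1, were added after seeing the data. Class shares, permutations and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.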

Results

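Sperm small RNA was profiled in adult male mice to ask whether infection with Toxoplasma gondii alters the RNA that sperm carry. Males aged 6 to 8 weeks received 100 µL of saline or the same volume with 50000 tachyzoites of the Pru strain, and sulfadiazine was given from day 5 to day 10 to establish a chronic infection. Cauda sperm were collected 25 days after infection by the protocol text, while the sample labels give week 4 after treatment. There were 5 libraries from control pools and 5 from infected pools, each pool of 2 mice. Libraries held 13061854 to 17639640 reads. The count table totalled 1582442 ± 440789 counts per control library and 2259156 ± 354092 per infected library (SD, n = 5, exact two-sided permutation p = 0.0317). Of all reads, 11.4% ± 2.77 were listed as mapped to the genome in controls and 14.5% ± 1.19 in infected pools (SD, n = 5, exact two-sided permutation p = 0.0556). Mapped reads outside any feature were listed as 132893424 to 200265856 per library, more than the total reads of any library. That column therefore cannot count single reads, and which mapping reads the mapped share covers is uncertain. Alignments assigned to genes came to 11.3% ± 4.03 of reads in controls and 15.4% ± 2.06 in infected pools (SD, n = 5), a difference of 4.12 percentage points that did not exceed the spread (exact two-sided permutation p = 0.0714). Without control replicate 1 the difference was 5.32 percentage points with an exact p of 0.0159. The table of control replicate 1 held 77.9% of its assigned alignments, while in the other 9 libraries the totals matched to within 0.1 percent.

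MicroRNA genes took most of the counts, and more of them in infected pools. Their share was 58.8% ± 7.79 in controls and 73.7% ± 2.16 in infected pools (SD, n = 5), higher in every infected pool than in every control pool (exact two-sided permutation p = 0.00794, the smallest possible, adjusted p = 0.0149 over 15 gene classes). The share of lincRNA genes was 2.43% ± 0.317 in controls and 1.15% ± 0.256 in infected pools, with the same exact p of 0.00794 and adjusted p of 0.0149. Protein-coding genes held 18.7% ± 4.16 and 13.1% ± 1.40, a difference that did not pass after adjustment (exact permutation p = 0.0476, adjusted p = 0.0649). Control replicate 1 held 11.6%, below every infected pool (11.9% to 15.4%), while the other controls (18.5% to 22.3%) were all above them. Ribosomal RNA made up 18.5% and snRNA 10.7% of control replicate 1, against control means of 5.63% and 3.25% that include it. The class of transcribed unprocessed pseudogenes held 0.233% ± 0.00969 and 2.90% ± 0.626 (exact permutation p = 0.00794, adjusted p = 0.0149), nearly all of it in Gm20257 (0.191% and 2.89%), whose values are close to those of Mir146 (0.203% and 3.02%). Without Gm20257 the class held 0.0418% and 0.0173%. The 10 genes of highest abundance were Mir99a, Mir26a-2, Mir26a-1, Mir10a, Mir148a, Mirlet7f-2, Mir10b, Mir143, Mirlet7g and Mirlet7c-2, and together they held 32.9% ± 4.61 of control counts and 43.2% ± 2.67 of infected counts (SD, n = 5, exact permutation p = 0.00794), with Mir26a-1 and Mir26a-2 sharing their counts.

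**Figure D1:**
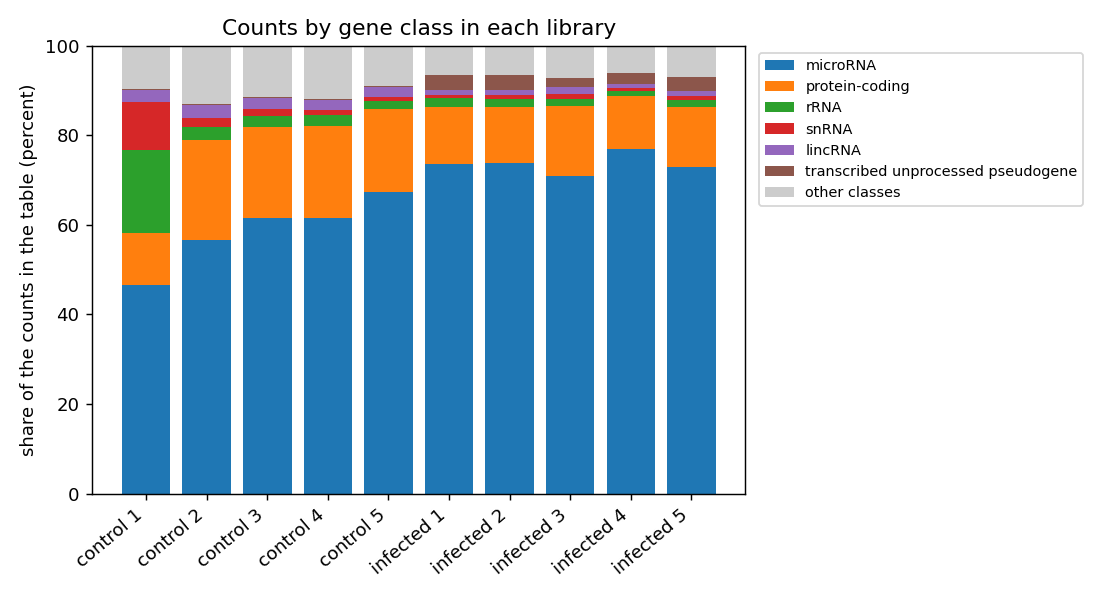
Share of the counts in the table (percent, vertical axis) by gene class for each of the 10 libraries (horizontal axis), as stacked bars. MicroRNA genes average 58.8% in controls and 73.7% in infected pools, and control replicate 1 stands apart with 18.5% rRNA and 10.7% snRNA.

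In infected pools 8 of 9 tested inflammation microRNAs and all 3 tested leukocyte microRNAs, of 5 in the table, were higher. Mir146 is in both of these lists. All 17 tested X-linked spermatogenic microRNAs, of 21 with deposited counts, and 16 of 19 tested spermatid mRNAs, of 36, were lower there. These are counts of single genes, since 0 of 21 lists passed camera with an estimated correlation, against 14 with its preset one. Mir146, a microRNA induced by inflammatory signalling, was 25.9-fold higher (log2 fold change 4.69 ± 0.30 SE) and higher in all 5 infected pools than in any control. In the X-linked Mir465 cluster, expressed in the testis, Mir465b-1 was 9.16-fold lower (log2 fold change -3.19 ± 0.43 SE) and Mir465c-1 7.79-fold. Prm2, which encodes a protamine that packs sperm DNA, fell by 3.51 on the log2 scale (-4.35 without infected replicate 3). Cd74 and the class I histocompatibility gene H2-K1 rose by 2.40 and 2.89. Of 5807 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2525 passed 0.05, with 1262 higher and 1263 lower in infected pools, and 3039 had an unadjusted p under 0.05. In 1562 of the 5807 tested genes the groups did not overlap, where chance gives 0.794% of genes. Fold changes are relative to TMM scaling, with a median gene at -0.06, and scaling by library totals instead moved that median to -0.92 and gave 457 higher and 2776 lower genes. Without infected replicate 3 the lower genes numbered 2097 and the higher 1138. The authors' deposited table lists 4354 of 36760 genes at FDR under 0.05, of which 1928 were among the genes tested here. Of these, 1892 were called here with the same sign and 36 were not called, while 633 genes called here did not pass there.

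**Figure D2:**
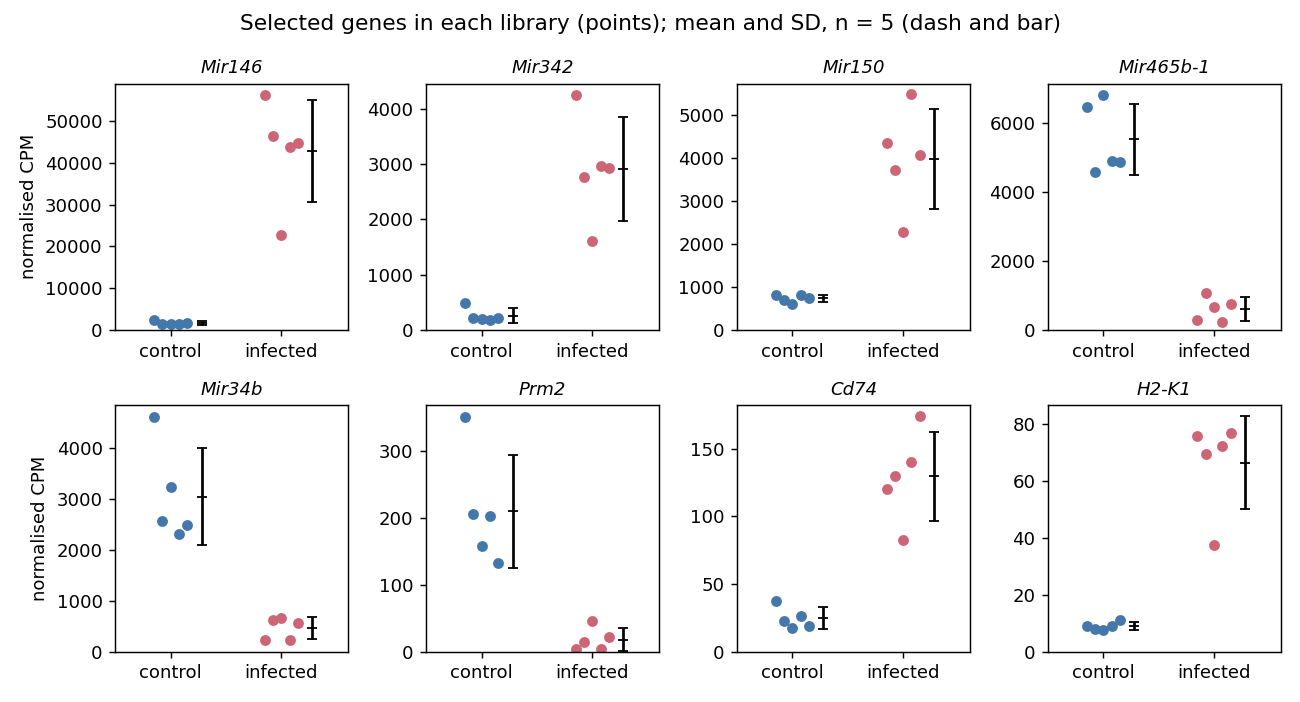
Normalised CPM (vertical axes, linear) of Mir146, Mir342, Mir150, Mir465b-1, Mir34b, Prm2, Cd74 and H2-K1 in control and infected libraries, one point per library, with mean and SD (n = 5) beside the points. Mir146 averages 1657 CPM in controls and 42840 CPM in infected pools, and Mir465b-1 5537 and 605 CPM, with no overlap of the groups.

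Among microRNA genes, 297 were tested and 201 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (209 adjusted over microRNA genes alone), 147 higher and 54 lower. Scaled on microRNA genes alone, 89 were higher and 85 lower, and scaled by library totals 84 of 165 called were higher. All 3 tested leukocyte microRNAs rose, and all 3 passed adjusted over the list alone: Mir146 had 1657 ± 428 CPM in controls and 42840 ± 12224 in infected pools, Mir342 259 ± 130 and 2909 ± 935, and Mir150, abundant in lymphocytes, 737 ± 85.4 and 3983 ± 1163 (SD, n = 5). Mir146 lies on chromosome 11 of GRCm38 from 43374397 to 43374461 on the minus strand, and its adjusted p was 6.72e-07. Gm20257, a pseudogene on chromosome 1 that was chosen after its values were seen, had almost the same values as Mir146 (1553 ± 401 and 40913 ± 11732 CPM). Of 9 inflammation microRNAs, 8 rose and none fell (8 higher and 1 lower adjusted over the list alone), against 4 higher and 1 lower both with library totals and scaled on microRNA genes alone, among them Mir146b with a log2 fold change of 2.02 ± 0.32 SE. Mir146 is in this list too, and its members Mir181a-1 and Mir181a-2 share counts. The list passed camera (adjusted p = 0.000295) but not with an estimated correlation (adjusted p = 0.331 with an estimated correlation). The 4 infected pools other than replicate 3 held higher Mir146, Mir342 and Mir150 than that pool.

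Most tested microRNAs and mRNAs of spermatogenic cells were lower. All 17 tested members of the X-linked spermatogenic list were lower, also adjusted over the list alone, with a median log2 fold change of -2.71 and of -3.46 with library totals. Mir881 fell by 2.71 (SE 0.43) and Mir465c-1, whose counts it shares with Mir465c-2, by 2.96 (SE 0.42), and the 2 Mir465b genes share counts as well. The camera test gave an adjusted p of 4.93e-11 (adjusted p = 0.331 with an estimated correlation). Of 19 tested spermatid and sperm mRNAs, out of 36 with deposited counts, 16 were lower and none higher. The same numbers passed adjusted over the list alone (camera adjusted p = 1.5e-07, adjusted p = 0.411 with an estimated correlation). Besides Prm2, with 209 ± 84.5 CPM in controls and 18.1 ± 17.6 in infected pools, Smcp of the sperm mitochondrial capsule fell by 2.28 (SE 0.61) and Odf1 of the outer dense fibres by 2.21 (SE 0.52), each by edgeR's quasi-likelihood test with adjusted p of 0.0092 and 0.00466. In the Mir34 and Mir449 family, which acts in the germ line and in multiciliated cells, 1 of 4 members rose and 2 fell (1 and 3 adjusted over the list alone). Mir34a rose by 3.31 (SE 0.44), Mir34b fell by 2.72 (SE 0.41) and Mir34c fell by 1.29 (SE 0.35), while Mir449a had a log2 fold change of -0.99 (SE 0.42) that did not pass except without infected replicate 3, where it was -1.26, and with library totals or microRNA genes alone. This list did not pass camera (adjusted p = 0.36).

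mRNAs of leukocytes and of the interferon-gamma response, which raises antigen presentation and host defence genes, were higher. Of 14 tested leukocyte mRNAs, out of 35 with deposited counts, 12 rose and none fell, also adjusted over the list alone (camera adjusted p = 1.27e-05, adjusted p = 0.331 with an estimated correlation). Cd74, the invariant chain of class II histocompatibility molecules, had 24.7 ± 8.01 CPM in controls and 130 ± 33.1 in infected pools (SD, n = 5), and H2-Aa rose by 2.34 (SE 0.39). Cd68 (log2 fold change -0.75, SE 0.53) and Itgam (0.65, SE 0.30), both named after their values were seen, did not pass. Without control replicate 1, 13 of 15 tested leukocyte mRNAs were higher and Cd68 was lower (log2 fold change -0.96, SE 0.36, adjusted p = 0.0343 by edgeR's quasi-likelihood test). Of 12 tested interferon-gamma response genes, out of 38 with deposited counts, 11 rose and none fell. Adjusted over the list alone, 11 were higher and 1 lower (camera adjusted p = 2.41e-05, adjusted p = 0.331 with an estimated correlation). Scarce members could pass the filter through the infected pools alone. Tgtp2, named after its values were seen, had 0.541 ± 0.585 CPM in controls and 11.6 ± 3.29 in infected pools (SD, n = 5). H2-K1, B2m and the guanylate-binding protein gene Gbp2 rose by 2.89 (SE 0.33), 2.46 (SE 0.37) and 2.84 (SE 0.45). With library totals the list medians were 0.68 for leukocyte mRNAs and 0.89 for interferon-gamma response genes, with 6 higher and 1 lower in each. These mRNAs are scarce in this small RNA preparation, at 8.95 ± 1.31 CPM for H2-K1 in controls.

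Markers of other cell types moved apart. Of 3 erythroid markers 2 rose, also adjusted over the list alone, Mir144 by 2.22 (SE 0.41) and Hbb-bs by 2.66 (SE 0.51). Of 3 tested epididymal epithelium markers, 2 fell, Adam7 by 1.45 (SE 0.35) and Crisp1 by 1.55 (SE 0.46), also adjusted over the list alone, while Crisp1 did not pass without infected replicate 5 (log2 fold change -1.42). Muscle and stroma markers went both ways, with 3 of 11 higher and 1 lower, the same numbers adjusted over the list alone, and 3 higher and 5 lower with library totals (camera adjusted p = 0.593): Mir199a-1, Mir143 and Mir145a rose by 2.32 (SE 0.29), 1.81 (SE 0.26) and 1.84 (SE 0.35), Myh11 fell by 0.71 (SE 0.26), and the collagen mRNA Col1a1 had a log2 fold change of -0.74 (SE 0.34) that did not pass. Myh11 and Col1a1 were named after their values were seen. Without control replicate 1 no marker of this list was lower.

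**Figure D3:**
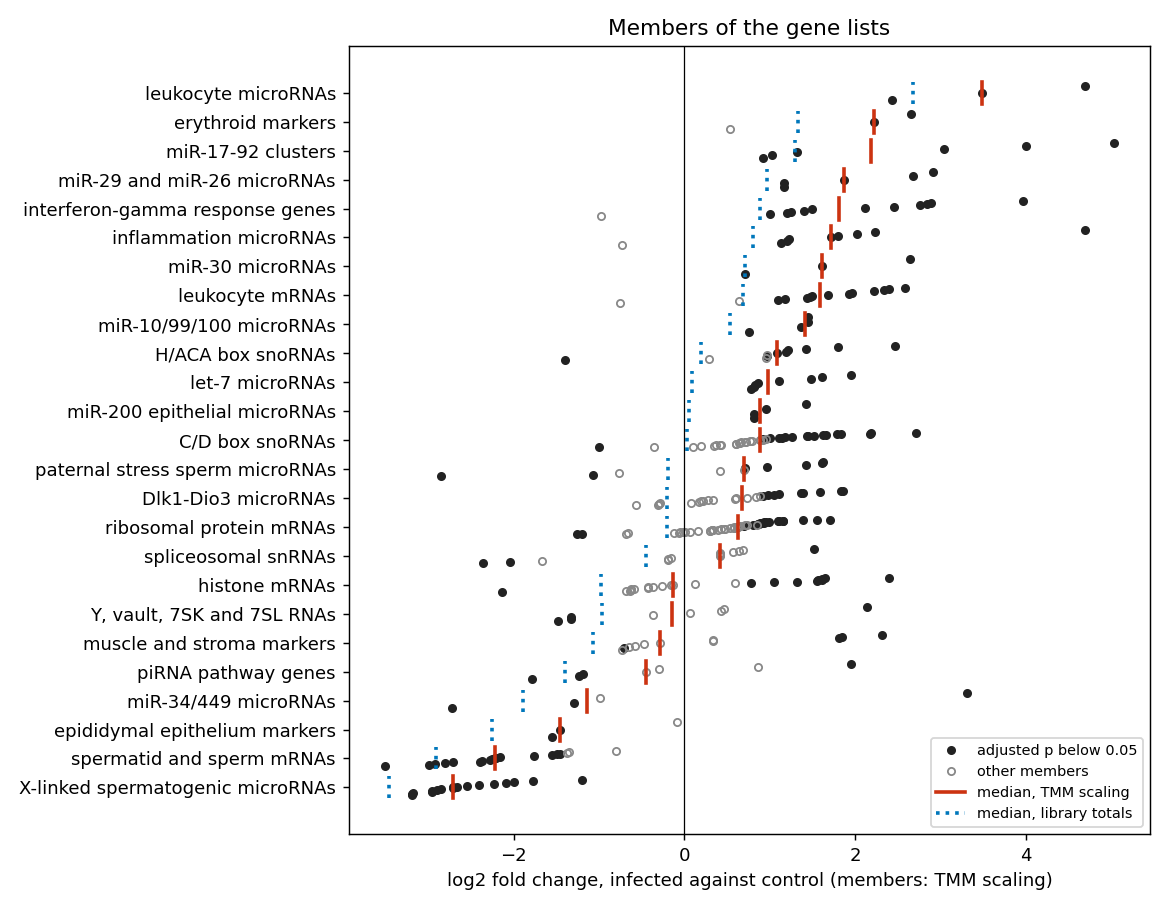
Log2 fold change of infected against control (horizontal axis, TMM scaling) of each tested member of the gene lists with at least 3 tested members (vertical axis), filled where the adjusted p is below 0.05, with the list median under TMM scaling (solid bar) and under library totals (dotted bar). X-linked spermatogenic microRNAs lie at a median of -2.71 and leukocyte microRNAs at 3.49, and the medians of paternal stress and Dlk1-Dio3 microRNAs, ribosomal protein mRNAs and the spliceosomal snRNA list, which also holds U3 snoRNAs, are above 0 with TMM scaling and below 0 with library totals.

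The let-7, miR-10/99/100, miR-29 and miR-26, miR-17-92, miR-30 and miR-200 lists were higher with TMM scaling, several of them close to 0 with library totals. All 8 let-7 genes rose (median 0.98), among them Mirlet7g at 1.95 (SE 0.23) and Mirlet7f-2 at 1.49 (SE 0.23), but the median was 0.09 with library totals, where Mirlet7c-1 and Mirlet7c-2 turned to -0.065 and -0.033. All 4 miR-10/99/100 genes rose, with Mir10a at 1.37 (SE 0.19), while Mir99a turned from 0.76 to -0.082 with library totals. All 5 miR-29 and miR-26 genes rose, Mir26a-1 and Mir26a-2 with shared counts and Mir29a at 2.68 (SE 0.31). All 6 tested genes of the miR-17-92 list, out of 14 listed, rose too, with Mir20b at 4.00 (SE 0.50, 4.598 without control replicate 1) and Mir363 at 3.05 (SE 0.35). The 6 were Mir106a, Mir20b, Mir363, Mir19b-2, Mir92-2 and Mir106b, and none is from the cluster of Mir17 to Mir92-1 itself. All 3 miR-30 genes rose, with Mir30b at 2.64 (SE 0.35). Mir30c-1 turned from 0.71 to -0.16 with library totals. All 4 miR-200 genes, typical of epithelia, rose with TMM scaling, with Mir200b at 1.42 (SE 0.26). Mir200a and Mir200c turned to -0.042 and -0.0062 with library totals. The same numbers passed adjusted over each list alone. With library totals fewer were higher and none lower: 3 of 8 let-7, 2 of 4 miR-10/99/100, 3 of 5 miR-29 and miR-26, 3 of 6 miR-17-92, 2 of 3 miR-30 and 1 of 4 miR-200 genes. Camera gave adjusted p of 0.000509 for let-7, 0.00695 for miR-10/99/100, 0.000406 for miR-29 and miR-26, 0.000101 for miR-17-92 and 0.0221 for miR-200 (adjusted p = 0.411 with an estimated correlation for let-7 and miR-200 and adjusted p = 0.331 with an estimated correlation for the others). Of 24 Dlk1-Dio3 microRNAs, 9 rose and none fell (also adjusted over the list alone) with TMM scaling, while with library totals 2 were higher and 6 lower (camera adjusted p = 0.0202, adjusted p = 0.651 with an estimated correlation). The paternal stress list held 5 higher and 2 lower of 10 (5 and 3 adjusted over the list alone, camera adjusted p = 0.36), with Mir532 at 1.62 (SE 0.34) and Mir375 at -2.86 (SE 0.43). Its higher members Mir30a, Mir30c-1 and Mir200b are also in the miR-30 and miR-200 lists. The paternal stress median turned from 0.70 to -0.19 with library totals.

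Other lists of small RNAs and mRNAs also held called genes. The annotation classes both nuclear tRNA entries as microRNA genes, and they count among those above. Both fell, also adjusted over the list alone: n-TStga1 by 2.93 (SE 0.36) and n-TSaga9 by 2.76 (SE 0.36). The first shares its counts with a gene model annotated as a microRNA. Among snoRNAs, which guide RNA modification, 16 of 37 C/D box genes rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 2.41e-05, adjusted p = 0.534 with an estimated correlation), and in the H/ACA box list, which took all Scarna genes and so holds C/D box and mixed ones too, 7 of 11 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0202, adjusted p = 0.475 with an estimated correlation). Of its 5 Snora genes 3 rose and none fell, and of its 6 Scarna genes 4 rose, Scarna9 by 1.80 (SE 0.34), and Scarna2 fell. With library totals the medians were 0.03 for the C/D box and 0.20 for the H/ACA box list, and without control replicate 1, 29 C/D box genes were higher. Of 51 ribosomal protein mRNAs, 19 rose and 2 fell with TMM scaling, also adjusted over the list alone, with Rpl7a at 1.71 (SE 0.38), while with library totals 2 were higher and 7 lower and without control replicate 1, 28 of 53 tested were higher (camera adjusted p = 0.00153, adjusted p = 0.525 with an estimated correlation). Histone mRNAs had 9 higher and 1 lower of 23, also adjusted over the list alone (camera adjusted p = 0.415), with Hist1h2ba, a testis histone, falling by 2.14 (SE 0.40). With library totals 2 histone mRNAs were higher and 12 lower (median -0.97). Without control replicate 1, 20 of 37 tested were higher, 2 lower and camera at its preset correlation gave an adjusted p of 0.0161. With an estimated correlation, run on all libraries only, camera gave an adjusted p of 0.808. piRNA pathway genes had 1 higher, Tdrd5 at 1.95 (SE 0.45), and 3 lower of 7, also adjusted over the list alone, and 0 higher and 4 lower with library totals (camera adjusted p = 0.575). The spliceosomal snRNA list, which took all Rnu symbols, had 1 higher and 2 lower of 14 (camera adjusted p = 0.415, 3 higher and 1 lower without control replicate 1), the higher one the snoRNA Rnu73b. It holds 6 snoRNAs of U3 and U73B, at a median of 0.42, and 8 other genes at -0.19, and Y, vault, 7SK and 7SL RNAs 1 higher (Vaultrc5, named after its values were seen) and 3 lower of 8 (camera adjusted p = 0.593), each also adjusted over the list alone.

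Some of the genes of highest fold change share counts with other entries, and the 12 lowest rest on control replicate 1. Besides Mir146, the highest were AC168274.1 at 6.24 (SE 0.73, 5.58 without infected replicate 3), Kars-ps1 at 5.59 (SE 0.52), Neurl2 at 5.21 (SE 0.58), Zfp980, Rex2, Zfp600 and Zfp981 at 5.11 to 5.13, Homer3 at 5.10 (SE 0.75, 4.43 without infected replicate 3), Slc6a2 at 4.69 (SE 0.51), Kars at 4.64 (SE 0.48) and Mir3965 at 4.54 (SE 0.45). Kars-ps1 shares its counts with 10 other entries, among them the models Gm15081, Gm15096 and Gm8366, and Zfp980, Rex2 and Zfp600 share theirs, so the source gene of these reads is uncertain. The 12 lowest were copies of 5S rRNA, from n-R5s117 at -8.91 (SE 2.25) to n-R5s101 at -5.15 (SE 1.83), together with the 5S models Gm25018, Gm22109 and Gm23647. They rest on control replicate 1: without it n-R5s117 was at -0.86, n-R5s106 turned to 0.50 and n-R5s101 to 2.37. With control replicate 1 left out and shared entries collapsed, chosen after seeing the data, 3375 genes passed, with 1705 higher and 1670 lower, and among the lowest in that fit were CT025710.1, Rbm12b1, Prm2, Narf, Rspo1, Mir465b-1, Mir465, Nkx2-4, Enox2 and Brix1, while Csnk2a1, Tll1 and Mir20b joined the highest. In all libraries Csnk2a1 had a log2 fold change of 4.53 (SE 0.42) and Tll1 of 4.23 (SE 0.41).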

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

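All tests of explanations in this part were chosen after the values they explain were seen. Within each group of 5 libraries, 318 values were examined for a library whose gap to the nearest other library exceeded 0.71 of the group's range, and 40 had one, 31 of them because of control replicate 1. Chance gives about 1 in 20 such groups for independent values that were not selected. The values examined include genes named for their extreme fold changes, among them 5S copies that share counts, so that rate is not a fair comparison.

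Control replicate 1 was far above the other controls in the share of rRNA (gap ratio 0.932), snRNA (0.889) and unprocessed pseudogenes (0.757). It was also far above in the 5S rRNA genes n-R5s117 and Gm25018 (0.902), Gm22109 (0.902), n-R5s106, n-R5s118 and n-R5s130 (0.994), n-R5s136 (0.915), n-R5s33 (0.950), Gm23647 (0.872) and n-R5s101, n-R5s102, n-R5s114, n-R5s119, n-R5s129 and n-R5s131 (0.866), in Rnu2-10 (0.796) and Snord17 (0.797), and in Mir342 (0.822), Mir20b (0.867), Crisp1 (0.762), Spink8 (0.718) and Odf2 (0.795). It was far below them in Rps19 (0.873), Mybl1 (0.861), CT025710.1 (0.915), Rbm12b1 (0.801), Rspo1 (0.911) and Nkx2-4 (0.982). In other libraries, control replicate 4 was high in Kars (0.833). Infected replicate 3 was high in the share of antisense genes (0.890) and low in Mir146 (0.725), Hbb-bt (0.741) and H2-K1 (0.858). Infected replicate 4 was low in the share of rRNA (0.713) and in n-R5s33 (0.922) and high in Mir10b (0.894), and infected replicate 2 was high in Mir141 (0.724).

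The first pattern is that of control replicate 1. Of 3175 genes with a mean control count of at least 20, 48 were at over 10 times the highest other control, 26 of them rRNA and 16 snRNA, and 434 were at under 0.1 of the lowest other control, against 0 or 1 gene past either limit for each other control. Counts taken up by rRNA and snRNA would lower the rest by one common factor, which the 434 genes, among them Mir27a with 354 counts against 5795 to 10962, argue against. An infected pool under a control label is argued against by Mir146, Mir342 and Mir150, all 3 of which were below the lowest infected pool, Mir146 at 1952 CPM of the table total against 20680 to 35901. A difference in how this library was prepared or its counts deposited stays open and was not tested, and no biological explanation was tested.

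The second pattern is the rise of leukocyte and interferon-gamma genes together with the fall of spermatid genes, and library totals or scaling as its whole cause are argued against: the log2 change of summed leukocyte mRNAs exceeded that of summed spermatid mRNAs by 3.99, a difference no scaling factor alters (exact two-sided permutation p = 0.00794, the smallest possible). A lower share of sperm RNA alone, which would raise every other cell type alike, is argued against for the mRNAs. Summed leukocyte mRNAs changed by 2.03 more on the log2 scale than 7 stroma mRNAs and by 1.62 more than 27 epididymal epithelium mRNAs (both exact permutation p = 0.00794). Part of the 2.03 is a fall of the stroma sum, by 0.66 from 677 ± 165 to 427 ± 99.4 CPM (exact permutation p = 0.0317). That sum is mostly collagen mRNA, with Col1a1 at 301, Col1a2 at 195 and Col3a1 at 144 CPM in controls. The epithelium sum is a weak comparison, since only 3 of the 27 passed the filter. It changed by -0.25 (exact permutation p = 0.548), from 69.3 ± 37.5 CPM in controls to 53.9 ± 9.09 in infected pools. Against this, the stroma-associated microRNAs Mir143, Mir145a and Mir199a-1, all 4 epithelial miR-200 genes and the erythroid Mir144 (4.65-fold) and Hbb-bs (6.32-fold) rose with TMM scaling. The other tested erythroid marker, Hbb-bt (1.45-fold), did not pass. More leukocyte RNA in the infected pools is a candidate explanation. Leaving out class II genes and any in the interferon-gamma list, 31 leukocyte mRNAs summed to 128 ± 23.2 CPM in controls and 332 ± 67.0 in infected pools (SD, n = 5). This is a log2 rise of 1.37 with no overlap. The 31 come from the list whose rise is to be explained, so their sum restates that rise and is no separate support. None of the 31 is in another list, and 15 had counts in every control library. The 3 most abundant on average were Lyz2 (34.1 ± 8.18 and 94.4 ± 24.9 CPM), Cd68 (24.6 ± 16.9 and 14.8 ± 6.97) and Ptprc (11.7 ± 3.31 and 24.7 ± 3.48). Of these, Cd68 goes against the explanation, and was lower without control replicate 1 at a log2 fold change of -0.96. The swim-up of motile sperm that the labels name could lower the number of leukocytes, and how far it did so was not tested. Blood carried over with the sperm and a change within sperm or the epididymis of infected mice stay open and were not tested.

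The third pattern is the 898 called protein-coding genes with a mean count of at least 20 outside the immune and spermatid lists. Reads shared with microRNAs would place exact 18-base matches to hairpins of abundant microRNAs mostly in the called genes, but 2.12% of called and 3.60% of 973 uncalled genes held one, a ratio of 0.588. Of the 19 called genes with a match, 6 moved with the matching microRNA. Only hairpins of the 143 tested microRNA genes with at least 100 CPM were searched, so reads from microRNAs without deposited counts stay open. Shorter or inexact matches and reads from repeats stay open as well, and so does a biological difference between infected and control mice.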

How the results depend on the processing

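The newer code, the collapsing of genes that share counts and the fit without control replicate 1 and with such genes collapsed were chosen after seeing the data, and the cause of the changes given here was not tested unless stated. Among 140 values of the main results under alternatives, 126 kept their direction and side of the threshold or stayed within 1.5 times. Library totals gave 457 higher and 2776 lower genes. With no filter 4346 genes passed and 2747 were lower. With fewer genes tested, the filter of 10 CPM left 1553 (766 higher, 787 lower) and microRNA genes alone 174 (89 and 85). No list, 0 of 21, passed camera with an estimated correlation, against 14 with the preset one, 13 by fry and 16 in the fit without control replicate 1 and with shared genes collapsed. Leaving out each library gave 2101 to 3494 genes, 1061 to 1753 higher, 960 to 2097 lower (the highest without infected replicate 3), 170 to 214 microRNA genes, 13 to 15 lists, a difference in microRNA share of 11.9 to 17.1 percentage points and in assigned reads of 2.64 to 5.32, which passed only without control replicate 1. Same-number correlations ran from -0.159 to 0.214. Control replicates 3 and 4 correlated best with the infected library of their own number, and control replicates 1, 2 and 5 did not. These few correlations cannot tell whether replicate numbers mark a shared batch. With the replicate number as a block 2101 genes passed, and the microRNA share difference of 14.97 had an exact sign-flip p of 0.0625, the smallest possible. The older quasi-likelihood code is the default of the edgeR version used and gave the same 2525 genes, and the newer gave 2537. Of 3257 log2 fold changes of named genes, 2975 kept their side of the threshold and direction, 197 lost the call, 13 gained it and 72 changed sign, many of them in genes that did not pass. Library totals and microRNA genes alone turned Mirlet7c-2 to -0.033 and -0.039, Mirlet7c-1 to -0.065 and -0.072, Mir99a to -0.082 and -0.082, Mir30c-1 to -0.16 and -0.17, Mir200a to -0.042 and -0.022, Mir379 to -0.69 and -0.69, Mir411 to -0.33 and -0.34, Mir381 to -0.56 and -0.56 and Mir148a to -0.092 and -0.069, and library totals alone turned Mir200c to -0.0062, Rny1 to -0.73, Hist1h4c to -0.10, Hbb-bt to -0.38, Snord104 to -0.28, Scarna17 to -0.54 and Rps6 to -0.39. Limma-voom turned Mir1a-1 to 0.24, Spink8 to 0.14, Rnu1a1 to 0.42, Rnu1b2 to 0.45 and Rnu1b1 to 0.45. The replicate block turned Mir1a-1 to 0.12, Rnu1a1 to 0.067, Rnu1b2 to 0.074 and Rnu1b1 to 0.076, and Spink8 was at 0.46 without control replicate 1 and with shared genes collapsed. Over left-out libraries Mir1a-1 ranged from -0.95 to 0.83, Spink8 from -0.39 to 0.44, Rnu2-10 from -1.96 to 0.19, Rnu1a1 from -0.32 to 0.56, Rnu1b2 from -0.37 to 0.62, Rnu1b1 from -0.37 to 0.63 and Rny1 from -0.053 to 0.33. By the direction camera gives, the spliceosomal list turned with library totals (median less that of all genes 0.47), and the list of Y, vault, 7SK and 7SL RNAs turned without control replicate 1, also with shared genes collapsed (0.38), with a range of -0.19 to 0.21 over left-out libraries. The 5S copies n-R5s106, n-R5s118 and n-R5s130 turned to 0.18 with limma-voom and ranged from -7.79 to 0.50 over left-out libraries, and n-R5s101, n-R5s102, n-R5s114, n-R5s119, n-R5s129 and n-R5s131 turned to 2.24 with limma-voom and 1.33 with the replicate block and ranged from -5.49 to 2.37, with n-R5s101 at 2.39 without control replicate 1 and with shared genes collapsed. The median count per gene and library was 1 to 3, so changes in scarce mRNAs are the least certain.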

Other observations

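The tests of splits in this part were chosen after the counts they test were seen. Several microRNAs outside the fixed lists, chosen after their values were seen, moved as far as the listed ones. Mir210, induced by low oxygen, was 13.8-fold higher with a wide spread between infected pools (306 ± 146 CPM in controls and 4231 ± 3913 in infected pools, SD, n = 5), and 8.99-fold higher without infected replicate 1. Mir107 and its relative Mir103-1 were 6.41-fold and 5.82-fold higher, Mir221 6.28-fold, Mir23a 5.11-fold, and Mir16-1 and Mir15b 4.91-fold and 4.55-fold. Mir184 and Mir128-1 were 6.26-fold and 3.75-fold lower. Each kept its direction with library totals, where the log2 fold change of Mir210 was 2.95 and that of Mir184 was -3.44, and passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment with each library left out.

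Other splits of the 10 libraries tested whether the counts of called genes exceed chance. Of 100 splits drawn from the 126 possible, only 1, the real one, gave as many called genes (2525), higher genes (1262) or lower genes (1263). The same held for called microRNA genes (201), and the highest of the other splits was 0 for each. This makes chance an unlikely source of these counts but does not exclude it. The other splits mix infected and control pools, so a group difference widens their spread and holds down their counts. For the number of lists past camera's preset correlation, 8 of the 100 splits gave 14 or more and the highest other gave 18, so chance cannot be excluded for that count.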
